A study of Mus musculus with 4 samples.

How the data were processed

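Total RNA from the ventricles of mice lacking the nuclear receptor ERRα (gene Esrra) and of wild-type mice, all at baseline, was measured on 4 one-colour Affymetrix oligonucleotide arrays, 2 per genotype. Per the labels' protocols, tissue was homogenized for RNA extraction, the RNA was purified, spiked with bacterial control transcripts, primed with an oligo-dT primer carrying a T7 promoter, and transcribed into biotin-labelled cRNA that was fragmented for hybridization. The deposited values are an intensity per probe set, linear and scaled by array: the mean after leaving out the top and bottom 2% of probe sets was 1501 on every array. The labels do not name the software, the summary method or the genome build, so background correction and the treatment of mismatch probes are unknown. For arrays, the number of arrays limits the precision, and 4 arrays were held. The quantitative PCR and pressure-overload experiments named in the study's design were not used here.

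Samples were grouped by the genotype in their titles. The labels number the samples 1 and 2 within each genotype and do not say whether a number joins a knockout sample to a wild-type sample, so the groups were compared without pairing; the number was tried as a block among the alternatives. The numbered samples are not stated to be separate animals, so the p-values of single probe sets measure the spread between these samples, which may be technical. The main test of gene lists and the test of genes near Esrra set genes against other genes. Their p-values do not measure the spread between samples.

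Gene symbols came from the annotation table that pairs the probe sets with genes, and 10839 of the 10855 probe sets with 1 symbol matched the RefSeq gene table of assembly GRCm38.p6, which was used only for names and for which genes neighbour each other. A further 396 probe sets had several symbols and 1237 had none. The 66 control probe sets were left out. Probe sets whose mean over the 4 arrays lay under the 40th percentile (a signal of 350.6) were left out, leaving 7453. Signals below 110, the 20th percentile of all values pooled, were set to that floor, and log2 was taken. Knockout and wild type were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, prior variance without trend), with Benjamini-Hochberg adjustment and a threshold of 0.05. A count without a model took probe sets with a difference of group means of at least 1.5-fold and both knockout arrays on the same side of both wild-type arrays. An exact permutation test of 2 against 2 arrays cannot go below a two-sided p of 0.333, so none is given for single genes.

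Before the data were examined, 29 gene lists were fixed, for the ERR family and its coactivators, energy metabolism, mitochondria, contraction, remodelling, stress, the clock, ribosomal proteins, sex-linked genes and markers of other cell types. Each list with at least 5 kept genes was tested with limma's camera at a preset inter-gene correlation of 0.01, on 5653 genes with the probe set of highest mean per gene, and adjusted over the 28 lists tested. The sex-linked list had 2 kept genes and was used only as a check. Camera with an estimated correlation and fry were run as alternatives. With 2 residual degrees of freedom, camera with an estimated correlation can hardly pass any list. It gave the same adjusted p of 0.814 to several lists, the 3 that passed in the main test included. Genes changed at least 1.5-fold without overlap were counted on the chromosome of Esrra and within 10 Mb of it, with Fisher's exact test, two-sided.

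Genes named in the text were chosen by a rule fixed before the data were examined. It took Esrra and members of its family past the threshold, up to 12 rises and 12 falls past the threshold, then, where a direction had fewer, the lowest unadjusted p among probe sets changed at least 1.5-fold without overlap, given as values that did not pass. Of each list it took members past the threshold, or else the 2 with the lowest unadjusted p. Genes named outside the rule are marked as such.

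The steps were tested on simulated data built on these arrays' means and spread. In the simulated knockout comparison with 7453 probe sets, 0.6% of probe sets changed by 1 on the log2 scale were called, 51.6% of those changed by 2, 81.6% of those changed by 3 and 92.4% of those changed by 4.5. Of 1194 calls, 63 were false. Each of these simulations held many changed probe sets, which eases the adjustment, and drew the spread without regard to signal level. The real comparison gave 1 call, and an Esrra probe set at log2 -3.08 did not pass (limma adjusted p = 0.179). The simulated shares therefore need not hold for it. On 5653 genes drawn independently and without any change, limma made 0 calls and camera called 0 lists in 10 simulations. Camera called a list shifted by 0.2 in 4 of 10 simulations and by 0.4 in 10 of 10. Genes of real lists can vary together, so these camera counts need not hold for them.

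The alternatives were other filters (none, or a 60th-percentile minimum), quantile normalization, median scaling, floors at the 5th and 40th percentiles, a pseudocount in place of the floor, the replicate block, each array left out, a variance prior that is robust and follows a trend with signal (for gene lists through cameraPR on the robust moderated statistics, since camera has no robust prior), the trend and the robust prior each alone, an ordinary linear model, leaving out probe sets with cross-hybridizing suffixes, and other set tests. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.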

Results

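The data were 4 expression arrays of mouse ventricle, 2 from mice lacking ERRα and 2 from wild-type mice, all at baseline. ERRα is an orphan nuclear receptor that regulates genes of mitochondrial energy metabolism. The comparison asked which transcripts differ between hearts with and without the receptor before any stress is applied. Each probe set had 1 scaled signal per array. Spearman correlations across probe sets within pairs of arrays ran from 0.911 to 0.923, and probe sets are not independent replicates. The 2 wild-type arrays were the closest pair, at 0.9231. The 2 knockout arrays correlated at 0.9175, below knockout replicate 1 with wild-type replicate 2 at 0.9186. Of 7453 probe sets tested, 1 passed the threshold, and it detected Esrra. The Y-linked genes Uty and Eif2s3y gave signal on all 4 arrays, from 281.8 to 439.1 for Uty and from 500.4 to 834.8 for Eif2s3y. The Y-linked Kdm5d lay between 23.8 and 80.3, Sry between 12.3 and 137.7 on 1 probe set and between 102.8 and 364.7 on the other, and Xist stayed at 106.2 or below. The ratio of 5' to 3' signal for β-actin was 0.694 and 0.813 on the knockout arrays against 0.966 and 0.909 on the wild-type arrays, and that of Gapdh was 0.994 and 0.968 against 1.04 and 1.01.

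Esrra itself fell in the knockout ventricles. The weaker of its 2 probe sets gave 2758 ± 99.2 in wild type and 69.4 ± 20.1 in knockout (signal, SD, n = 2 each). Both knockout arrays lay at the floor, so the signal was at least 25.1-fold lower (log2 -4.65, SE 0.19, limma adjusted p = 0.0441). The stronger Esrra probe set gave 8318 ± 396 and 986 ± 90.7, an 8.45-fold difference (log2 -3.08, SE 0.21) that did not pass over all probe sets (adjusted p = 0.179). Where either lies relative to the deleted part of the gene is not stated in the labels. With floors at the 5th and 40th percentiles the weaker probe set had log2 changes of -5.34 and -3.02. Its call was lost without any 1 array. Its log2 change then stayed between -4.68 and -4.61, in part because both knockout arrays lay at the floor. Over 16 alternatives its adjusted p ran from 0.00243 to 0.752.

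**Figure D1:**
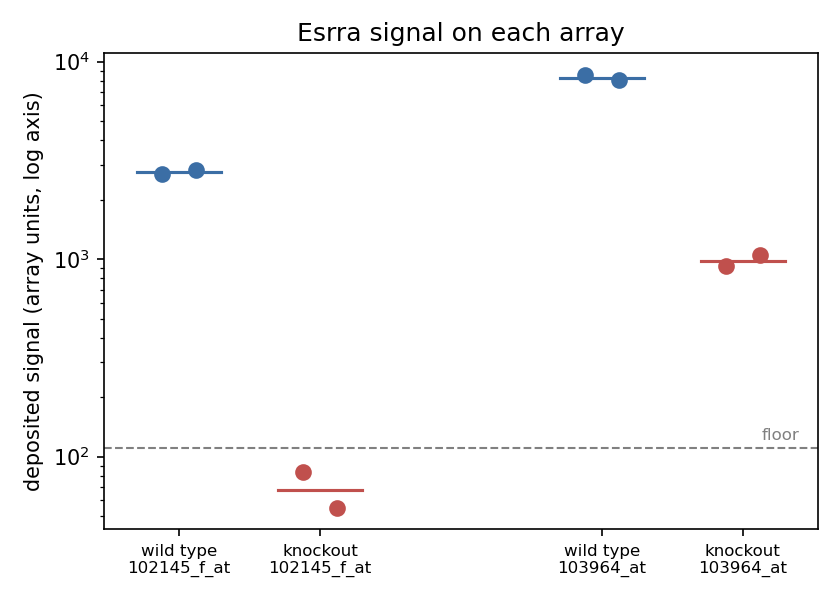
Deposited signal of the weaker (left) and the stronger (right) Esrra probe set on each array (log axis, array units). Each point is 1 array, horizontal bars are the geometric means of 2 arrays, and the dashed line is the floor of 110; the knockout points of the weaker probe set lie at 83.6 and 55.2.

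Among the other members of the ERR family and coactivator list, none passed. Ppargc1a, which encodes the coactivator PGC-1α, gave 402 ± 46.8 in wild type and 691 ± 144 in knockout (log2 0.77, SE 0.25), and Nr1h3, the liver X receptor α, gave 853 ± 28.2 and 537 ± 155 (log2 -0.70, SE 0.28); both were singled out after their values were seen. The list of 13 genes had a median of 0.13 and a mean of -0.13, and camera gave it a downward direction (adjusted p = 0.893). 1 member, Esrra, passed when adjusted over the list alone, against 0 over all probe sets among those the list test used, since the list test used the stronger probe set.

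Beyond Esrra, no gene passed, so the following are values that did not pass (limma adjusted p 0.430 to 0.622). The 12 genes with the clearest higher signal in knockout lay at least 3.05-fold above wild type, and all started from low wild-type signals of 97.2 to 404. Cxadr, the coxsackievirus and adenovirus receptor, gave 118 ± 3.89 in wild type and 609 ± 101 in knockout (n = 2 each), and Ptgfr, the prostaglandin F receptor, gave 270.1 ± 116 and 1619 ± 248. Tpbpa, with 1 wild-type array below the floor, gave 97.2 ± 43.8 and 1096 ± 318, at least 9.03-fold, Htr1b, a serotonin receptor, 192 ± 39.0 and 752 ± 31.1, and Tex2 351 ± 29.8 and 1330 ± 109. Pfkp, the platelet phosphofructokinase, and G6pd2, a glucose-6-phosphate dehydrogenase, had log2 differences of 1.61 and 1.75, while Gdpd5, Psmg3, Pcsk4, Galnt6 and Pmf1 had 2.30, 2.13, 1.96, 2.24 and 1.73. Galnt6 also had 1 wild-type array below the floor. With the floor at the 40th percentile the log2 differences of Cxadr, Tpbpa, Htr1b, G6pd2, Gdpd5, Pcsk4, Galnt6 and Pmf1 were 0.83, 1.65, 1.14, 0.65, 1.12, 1.28, 0.82 and 0.73, whereas Pfkp stayed at 1.61 and Ptgfr, Tex2 and Psmg3 had 2.22, 1.90 and 1.90. A stronger probe set for Pfkp had a log2 difference of 0.47, and those for Psmg3 and Pcsk4 had 0.07 and -0.20.

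The 11 genes with the clearest lower signal lay 2.39- to 4.91-fold below wild type. Cd59a, an inhibitor of complement, gave 7442 ± 581 in wild type and 2251 ± 393 in knockout (log2 -1.73), Plbd1 gave 5627 ± 63.3 and 2051 ± 335 (log2 -1.47), and Gga2, an adaptor of Golgi sorting, gave 4227 ± 208 and 1768 ± 52.6 (log2 -1.26). Lipa, the lysosomal acid lipase, Pea15a, Map3k11 and Tollip had log2 differences of -1.87, -1.76, -1.70 and -1.80; a second Tollip probe set had 0.33. Zfp622, Acsm2, Rev3l and Abca4 had -1.88, -1.34, -1.46 and -2.29. With the floor at the 40th percentile Lipa had -0.72 and Map3k11 -1.04.

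In total, 506 probe sets had an unadjusted p under 0.05, 308 higher and 198 lower, and by the count without a model 823 had changed by at least 1.5-fold without overlap, 510 higher and 313 lower (62.0% higher). After quantile normalization 396 were higher and 414 lower, and after median scaling 440 and 387. Groups did not overlap for 37.4% of probe sets, where chance gives 33.3%. From the strongest to the weakest of 5 equal bins of signal, the median log2 difference went from -0.05 to 0.14, and the replicate SD from 0.16 to 0.48.

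Genes of respiratory chain complex I, the NADH dehydrogenase, were lower in knockout. Of 27 genes, 25 had a lower mean in knockout and 15 were lower without overlap, with a median log2 difference of -0.18 (camera adjusted p = 0.0157; adjusted p = 0.814 with an estimated correlation). No single member passed, over all probe sets or adjusted over the list alone; Ndufb3 had the lowest p, with 15380 ± 1313 in wild type and 10361 ± 1423 in knockout, and Ndufs3 gave 51210 ± 5484 and 38377 ± 1577. The call ended after quantile normalization (median -0.11, adjusted p = 0.253), without probe sets with cross-hybridizing suffixes (-0.15, 0.0536) and without knockout replicate 1, wild-type replicate 1 or wild-type replicate 2 (medians -0.13, -0.14 and -0.14, adjusted p 0.281, 0.0636 and 0.1002). Over 18 alternatives the adjusted p ran from 4.19e-04 to 0.814, and the actin and Gapdh ratios of 5' to 3' signal were lower on the knockout arrays.

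The other mitochondrial lists did not pass. Complexes II to IV with cytochrome c had a median of -0.09 over 26 genes (adjusted p = 0.397), with Cox17 at log2 -0.39 and Cox8b at -0.42 and -0.26 on its 2 probe sets. ATP synthase and nucleotide exchange had 0.04 over 17 genes (0.483); its Atp5pb and Atp5j2 probe sets gave 1121 ± 3.11 against 2027 ± 184 and 228 ± 44.5 against 495 ± 164. Fatty acid uptake and oxidation had -0.15 over 27 genes (0.139), with 20 lower. Its Etfdh, which passes electrons from β-oxidation to the respiratory chain, gave 12213 ± 47.3 in wild type and 6640 ± 1629 in knockout, and Hadhb, a subunit of the trifunctional protein, 85128 ± 9290 and 61559 ± 4317. This list passed with no filter (adjusted p = 0.0491), with the trend and robust prior (0.0389), without wild-type replicate 1 (median -0.30, adjusted p = 0.0253) and without knockout replicate 2 (-0.32, 0.0168), and it had an adjusted p = 0.814 with an estimated correlation. Its median was -0.02 without knockout replicate 1 (0.848) and -0.06 without wild-type replicate 2 (0.671). Pyruvate oxidation and the citric acid cycle had 0.02 (0.992), with Dlat at 1.27 on 1 probe set and 0.11 on the stronger other, and Idh3a at 0.38. Glucose uptake and glycolysis had 0.00 (0.841), with Slc2a1 at 1.33 from a wild-type signal of 203. Lipid synthesis and storage had 0.03 (0.923), with Scd1 at 0.81 on a weak probe set and 0.15 on a stronger one and Me1 at 0.65. The creatine and adenylate shuttle had -0.13 (0.483), with Ak1 at -0.40 and Ak4 at -0.56 and 0.20 on its 2 probe sets. Mitochondrial biogenesis had -0.12 (0.369), with Polrmt at 2.08 on a weak probe set and 0.21 on a stronger one and Mfn1 at 0.42 and 0.16. The antioxidants had -0.11 (0.346), with Gsta4 at -1.06 and Cat at -0.45 and 0.20 on its 2 probe sets.

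Interferon-response genes and genes of the endoplasmic reticulum and proteasome were the other lists that fell. Both lists hold Psmb8 and Psmb9, whose signals were highest on wild-type replicate 2 (2279 and 1151). The interferon list had a median of -0.36 over 17 genes (adjusted p = 0.0157; adjusted p = 0.814 with an estimated correlation), with 15 lower and 6 lower without overlap. Isg15 gave 1089 ± 388 in wild type and 609 ± 102 in knockout, and Mx2 421 ± 23.8 and 560 ± 8.13. The inducible GTPase Iigp1 gave 21144 on wild-type replicate 2 and 1756, 2161 and 1863 on the other arrays, and Igtp gave 4136 there and 351 to 588 elsewhere; both were singled out after their values were seen. Without wild-type replicate 2 the median was -0.0808 (adjusted p = 0.570), without knockout replicate 2 it was -0.41 (0.293), without probe sets with cross-hybridizing suffixes -0.37 (0.0983), and -0.32 both with the mean of a gene's probe sets (0.109) and without the inducible GTPase genes (0.0580). Over 19 alternatives the adjusted p ran from 4.99e-06 to 0.814.

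The endoplasmic reticulum and proteasome list had a median of -0.17 over 35 genes, 27 of them lower (adjusted p = 0.0157; adjusted p = 0.814 with an estimated correlation). Ddit3, the stress-induced factor CHOP, gave 706 ± 236 in wild type and 272 ± 84.6 in knockout, and Psma1, a proteasome core subunit, 1585 ± 91.9 and 1078 ± 101; neither passed alone. The median was -0.12 without knockout replicate 1, -0.18 without wild-type replicate 1 and -0.15 without wild-type replicate 2 (adjusted p 0.281, 0.0588 and 0.108), -0.13 after quantile normalization (0.111) and -0.14 with the stricter filter (0.0928), and for the endoplasmic reticulum and the proteasome members alone -0.10 and -0.17 (0.211 and 0.0540). Over 20 alternatives the adjusted p ran from 0.00146 to 0.814. The actin and Gapdh ratios of 5' to 3' signal were lower on the knockout arrays, beside the falls of this list and of complex I. The interferon list did not follow them in the same way. Wild-type replicate 1 had the highest ratios (0.966 and 1.04) but an interferon median of -0.15, near the knockout arrays at -0.22 and -0.29.

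**Figure D2:**
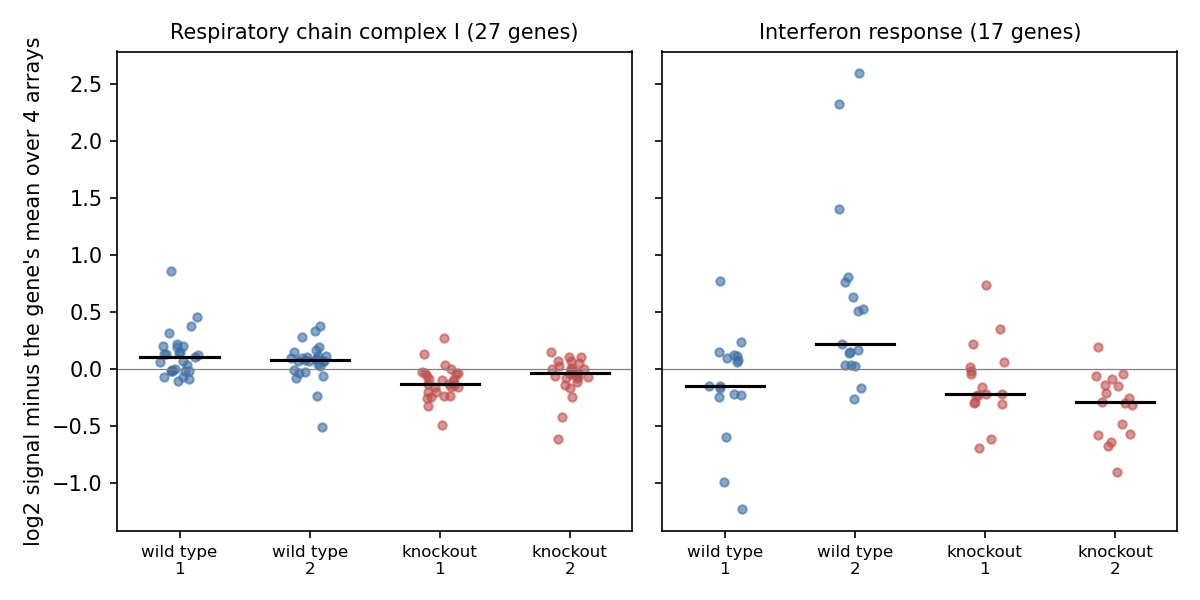
Log2 signal of each gene of the complex I list (27 genes) and the interferon list (17 genes) minus its mean over the 4 arrays, by array; black bars are medians. The complex I medians were 0.10 and 0.08 on the wild-type arrays and -0.13 and -0.04 on the knockout arrays, and the interferon median was 0.21 on wild-type replicate 2 and -0.15, -0.22 and -0.29 on wild-type replicate 1 and knockout replicates 1 and 2.

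The contraction lists did not pass. The sarcomere list had a median of -0.12 over 24 genes (adjusted p = 0.369; -0.03 without knockout replicate 1 and -0.27 without knockout replicate 2), with Csrp3, the muscle LIM protein, at 51699 ± 7247 against 29055 ± 2596 and Myl4, the atrial light chain, at 1273 ± 312 against 2932 ± 1034 (log2 1.18, and 0.58 on a second probe set). Calcium handling had a median of 0.05 over 15 genes and a downward camera direction (0.483); Hrc, a sarcoplasmic reticulum calcium-binding protein, gave 31020 ± 3651 in wild type and 14395 ± 416 in knockout (log2 -1.10), and Sri, sorcin, 2303 ± 60.2 and 1565 ± 160. The fetal and hypertrophy program had -0.05 over 23 genes (0.499), with Acta1, skeletal α-actin, at log2 -1.04 and Fhl1 at -1.20 and -0.95 on its 2 probe sets. Ion channels and conduction had 0.21 over 15 genes (0.369), with Hcn2, a pacemaker channel, at 1.26 and 0.34 on its 2 probe sets and Kcnd2 at 0.96.

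Markers of other cell types and chambers were measured in the same arrays, and none of these lists passed in the main test. The atrial list had a median of 0.67 over 9 genes (adjusted p = 0.0950), with 7 higher. It passed with the trend and robust prior (0.0462) and with the replicate block (0.0366), and had an adjusted p = 0.814 with an estimated correlation. Its median was 0.30 without wild-type replicate 2. Clu gave -0.97 and -0.88 on its 2 probe sets and Stard10 1.06 on the log2 scale; 2 genes, Clu and Stard10, passed when adjusted over the list alone, against 0 over all probe sets. Myl4, Myl7 and Nppa, singled out after their values were seen, lay at 1.18, 0.79 and 0.72. The adipocyte list had 0.46 over 9 genes (0.227), but 0.15 without wild-type replicate 1, 0.26 without wild-type replicate 2 and 0.06 with the stricter filter, with Adipoq, adiponectin, at 243 ± 76.9 against 645 ± 57.8 and Cidea at 2148 ± 103 against 1269 ± 64.5. Extracellular matrix genes had 0.09 over 27 genes (0.312), 0.11 to 0.21 without each array and 0.20 with the stricter filter, with Lum at 3300 ± 720 against 5650 ± 772 and Col1a2 at log2 0.74 and 0.26 on its 2 probe sets. Smooth muscle markers had -0.02 over 11 genes (0.757); Acta2, smooth muscle α-actin, gave 3522 ± 867 against 14834 ± 5542 and passed adjusted over the list alone, 1 against 0 over all probe sets, with Kcnj8 at -0.46. Endothelial markers had -0.08 (0.140) and -0.22 to -0.03 without each array, with Tie1 at -0.57 and -0.25 and Aqp1 at 1.08 on a weak probe set and -0.03 on a stronger one. Immune markers had 0.13 (0.483), with Cd52 at 0.30 and Tyrobp at -0.43. Nerve markers had -0.09 (0.483), with Ncam1 at 0.98 on a weak probe set and -0.50 on a stronger one and Mal at -0.64. Erythroid markers had 0.12 (0.494), but 0.40 without wild-type replicate 1 (0.0549) and -0.20 without wild-type replicate 2 (0.504); Car2 gave 674 ± 33.2 against 1438 ± 122 and passed adjusted over the list alone, 1 against 0 over all probe sets, and Slc4a1 was at -0.27.

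**Figure D3:**
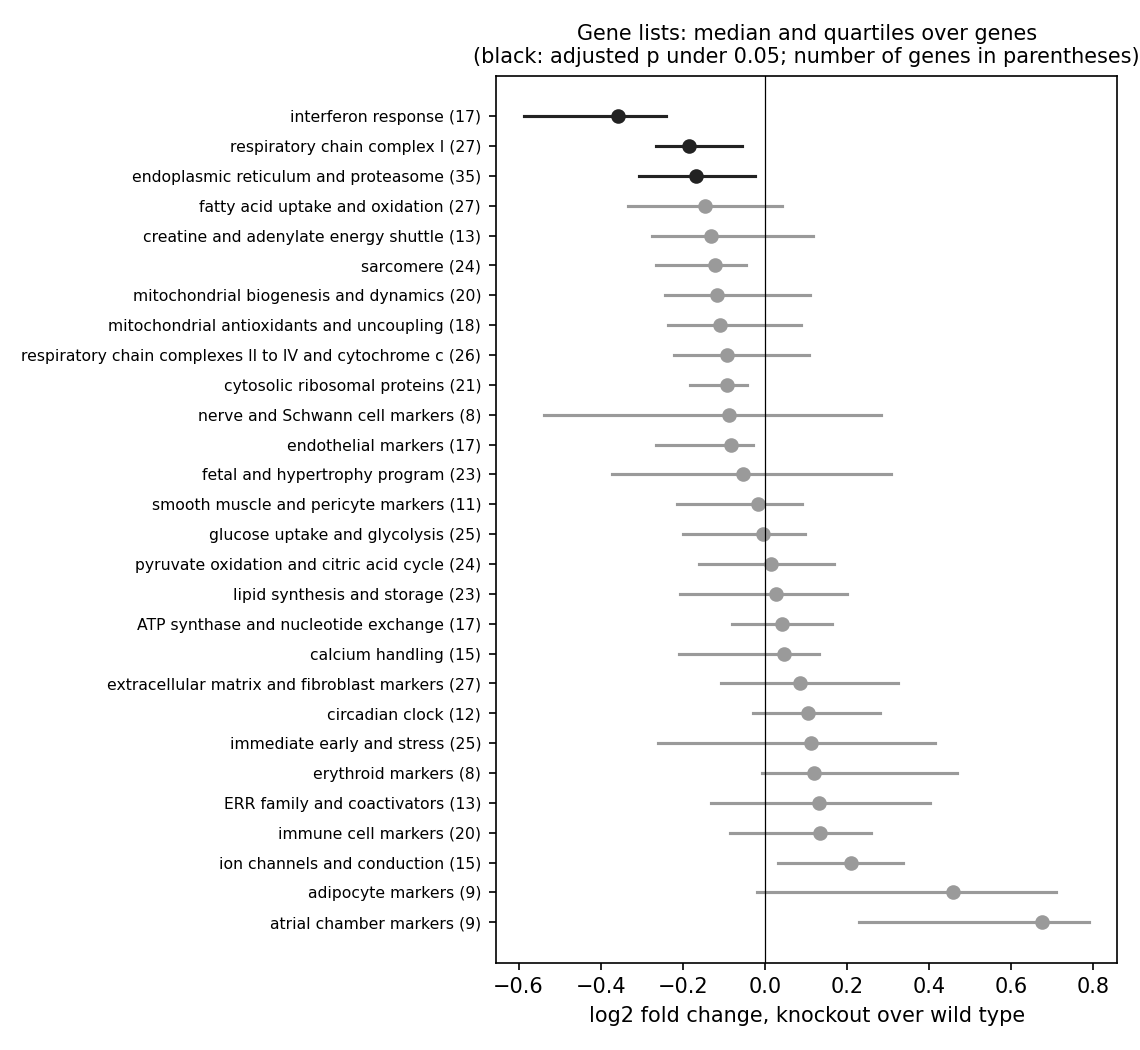
Median log2 fold change (knockout over wild type) of the 28 gene lists, with lines from the lower to the upper quartile over genes and the number of genes in parentheses. Black marks the 3 lists with an adjusted p under 0.05, at -0.36, -0.18 and -0.17; the atrial list has the highest median, 0.67.

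Of the remaining lists, immediate early and stress genes had a median of 0.11 over 25 genes (adjusted p = 0.483), but 0.39 without knockout replicate 1 (0.281) and -0.03 without knockout replicate 2 (0.968). Fos gave 183 ± 41.9 in wild type and 697 ± 244 in knockout, and Junb 853 ± 117 and 1395 ± 64.4 (log2 0.72, and 0.46 on a second probe set). Clock genes had 0.11 (0.757), with Tef at -0.47 and Dbp at 0.46, and cytosolic ribosomal proteins -0.09 (0.176), with Rps29 at 0.96 and Rpl22 at 1.33 on weak probe sets and at -0.14 and -0.37 on stronger ones. The ribosomal list passed without knockout replicate 2 (median -0.19, adjusted p = 0.0168) and had a median of 0.01 without knockout replicate 1 (0.979). Without 1 array or another the median moved by over 1.5 times or turned its sign in 25 of the 25 lists that did not pass. It turned in 15 of them. Of the lists that passed, the interferon median also moved by over 1.5 times. Those of complex I and of the endoplasmic reticulum and proteasome did not. The median, mean or test differed in sign for 5 lists, those of calcium handling, smooth muscle, glycolysis, the ERR family and lipid synthesis. At an unadjusted p under 0.05, 7 lists differed, and 0 passed with an estimated correlation or by fry. Camera with an estimated correlation had 2 residual degrees of freedom, so its result cannot tell the lists apart. Whether such a limit holds for fry was not examined, and fry passed none of the lists called in the main test.

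Genes near Esrra were examined because a targeted allele can carry flanking DNA of another strain. On its chromosome, 27 of 206 genes (13.1%) had changed at least 1.5-fold without overlap, against 559 of 5439 elsewhere (10.3%; odds ratio 1.32, Fisher's exact p = 0.1996). Within 10 Mb, 15 of 114 had done so (odds ratio 1.32, Fisher's exact p = 0.350). Both counts include Esrra itself. Without Esrra they were 26 of 205 on the chromosome (odds ratio 1.27, Fisher's exact p = 0.292) and 14 of 113 within 10 Mb (odds ratio 1.23, Fisher's exact p = 0.437). The chromosome-wide odds ratio was 1.60 with no filter (exact p = 0.00469) and 1.56 without wild-type replicate 1 (exact p = 0.00888), and the ratio within 10 Mb was 1.75 without wild-type replicate 2 (exact p = 0.0102); without knockout replicate 1 the ratios were 0.877 and 0.859.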

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

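All alternatives were chosen before the data were examined except the trend and the robust prior each alone, the separate endoplasmic reticulum and proteasome lists, the interferon list without GTPases, and the counts and list without Esrra. The cause was not tested for the changes below, beyond fewer probe sets or arrays where those were left out. In every setting, only Esrra probe sets passed. Their number was 0 with no filter, floors at the 5th or 40th percentile, the replicate block, an ordinary model or no cross-hybridizing suffixes (which leaves out the weaker Esrra probe set), 2 with the stricter filter, the trend and robust prior or the trend alone (1 with the robust prior alone), and 0 without each array in turn. For the weaker Esrra probe set the log2 change was -4.65 with no filter, the replicate block and the ordinary model (adjusted p 0.118, 0.263 and 0.123), -5.34 and -3.02 at the floors (0.125 and 0.0574), and -4.68 to -4.61 without each array. For the stronger it was -3.08 with the stricter filter and the trend and robust prior, where it passed (0.0156 and 0.00590). The 1.5-fold count was 1488 with no filter, 327 with the stricter filter and 1383 to 1523 without each array, since 1 array overlaps less often than 2.

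The sample numbers gave no sign of pairing: deviations of same-numbered arrays correlated at 0.0113 across probe sets over 2 pairs, which cannot be tested. With the replicate block Esrra had an adjusted p of 0.263, the complex I list 0.0247, the interferon list 0.0152, the endoplasmic reticulum and proteasome list 0.0247 and the atrial list 0.0366, which passes. The block was not run for the counts that use no model, which it leaves as they are.

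Lists past the threshold numbered 1 after quantile normalization or without cross-hybridizing suffixes, 5 with the trend and robust prior or the trend alone (the fatty acid and atrial lists besides), 3 with the robust prior alone, 0 with an estimated correlation or fry, and 0 to 4 without each array. The complex I median was -0.11 after quantile normalization, -0.15 without suffixes, -0.18 with an estimated correlation or fry, and -0.19 to -0.13 without each array. The endoplasmic reticulum and proteasome median was -0.14 with the stricter filter, -0.13 after quantile normalization, -0.17 with an estimated correlation or fry, -0.10 and -0.17 for its parts alone, and -0.18 to -0.12 without each array. The interferon median was -0.37 without suffixes, where its call and that of complex I ended (adjusted p 0.0983 and 0.0536), -0.36 with an estimated correlation or fry, -0.32 with the mean of probe sets or without the GTPases, and -0.46 to -0.0808 without each array. Odds near Esrra passed at 1.60 with no filter and 1.56 without wild-type replicate 1 on the chromosome and at 1.75 without wild-type replicate 2 within 10 Mb, over 0.877 to 1.56 on the chromosome and 0.859 to 1.75 within 10 Mb without each array. Leaving aside the trend and the robust prior each alone, there were 451 alternatives for the uncalled lists. Of these, 444 left them uncalled, 7 passed and 33 turned the direction. With the trend alone the fatty acid and atrial lists passed besides (camera adjusted p 0.0418 and 0.0477). The 325 alternatives for the named genes, counted in the same way, changed no direction and no call. These genes were picked for groups that do not overlap, so leaving out an array could not turn their direction. Their constant direction is therefore no support for them. The 12 named higher genes began from wild-type signals of 97.2 to 404. The median replicate SD on the log2 scale was 0.48 in the weakest of 5 bins of mean signal and 0.16 in the strongest. Among weak probe sets this spread limits what 4 arrays can resolve.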

Other observations

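The tests of single arrays, immune markers, interferon genes on wild-type replicate 2, atrial genes, the share of higher probe sets and other splits were chosen after the result was seen; the level-matched tests of complex I and the test of chaperones were added after seeing the data. For the matched test before quantile normalization and for the chaperones, the conditions were written before the result, though quantile-normalized medians and some chaperone genes had been seen. The genes in this paragraph were chosen after their values were seen, as the strongly expressed ones. Of 746 probe sets above the 90th percentile of mean signal, where replicates varied least, 32 had changed by at least 1.5-fold without overlap, 12 higher and 20 lower, and none passed. Ndrg4 gave 14504 ± 2704 in wild type and 33300 ± 11658 in knockout, Rab5if 6545 ± 280 and 12437 ± 1004, and Perp 7923 ± 1988 and 13420 ± 318 (signal, SD, n = 2 each). Lower in knockout were Smyd1, a muscle methyltransferase, at 15518 ± 751 and 8394 ± 3874, Gsto1 at 11310 ± 511 and 6147 ± 1869, Saraf, a regulator of calcium entry, at 13290 ± 371 and 8710 ± 611, and Map1lc3a, an autophagy protein, at 30193 ± 5076 and 18798 ± 1421. Wdr92 had 65409 ± 41560 and 19210 ± 4597, a spread close to its difference.

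The cytosolic chaperone genes Hsp90aa1, Fkbp4 and Bag3 had log2 differences of -0.92, -0.72 and -0.67, which raised the hypothesis that chaperones fall together. Over the 19 remaining chaperone genes the median was -0.13, with 12 lower (camera, n = 19 genes, p = 0.257). A p above the threshold does not show that these genes were alike in both groups, so the condition written beforehand against the hypothesis was too strict and it stays open.

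The complex I list was lower on both knockout arrays. A trend of the differences with signal level could account for part of it. Random lists matched on signal level had a median of -0.06, and the list's -0.18 lay at the 0.89th percentile of 10000 such lists. After quantile normalization it was -0.11 against a matched median of 0.00, at percentile 2, while the camera call ended as the difference shrank. Random lists hold unrelated genes, and medians of genes that vary together can spread more. The percentiles argue against the trend as the whole account only if the complex I genes vary independently. No single array made up the whole of the lower median, since the highest median without an array in turn was -0.13. This condition was written after the result was seen. With 2 arrays per group it cannot exclude that 1 array adds to the difference. Correlated expression of these genes stays open. Camera with an estimated correlation gave an adjusted p of 0.814, but with 2 residual degrees of freedom it passed 0 lists and cannot decide this. Fry also passed 0 lists. The actin and Gapdh 5' to 3' ratios that go with genotype stay open too. The loss of ERRα may lower these genes, a hypothesis that 2 arrays per group cannot separate from the rest.

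The interferon list may rest on wild-type replicate 2: without it the median was -0.0808. Of its 17 genes, 10 were above all 3 other arrays there, with a median difference of 0.29 (SE 0.265 over genes). A shared rise of immune markers in that sample was argued against by 20 such genes, with a median difference of -0.14 (SE 0.0989 over genes). More immune cells of all kinds required 0.3, in a test chosen after the result was seen. The SE is over genes on that array and does not measure the spread between samples. Of the 20 markers, 5 were above all 3 other arrays there. A rise of some immune cell types without the others was not tested. An interferon response in the heart behind that array, or another difference of that sample, was not tested.

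The atrial list did not pass (adjusted p = 0.0950) but did with the trend and robust prior (0.0462) and with the replicate block (0.0366). Its median of 0.67 moved to 0.30 without wild-type replicate 2. For the higher signal of some members, more atrial tissue in the knockout samples is a candidate explanation. Of Sln, Myl7, Myl4, Nppa and Bmp10, 4 were higher on both knockout arrays. Myl7, Myl4 and Nppa belong to the same list and were picked after their values were seen, so their rise is not a test. Sln was low on all arrays (147.6 and 411.2 in knockout, 110.6 and 80.0 in wild type), and Bmp10 was not separated. Clu and Kcna5 (log2 -0.38), also on the atrial list, were lower in knockout without overlap, while the other kept members had higher means. With 2 samples per group, atrial tissue and a change of these genes within ventricular muscle cannot be told apart.

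More of the 1.5-fold probe sets were higher than lower, 62.0%, and 48.9% were higher after quantile normalization. A trend by signal level is a candidate explanation: in the strongest of 5 equal bins of signal 32 were higher and 43 lower, and in the weakest 242 and 119. Quantile normalization equalizes the arrays by construction and median scaling alone gave 53.2%, so whether that trend accounts for the excess stays open. Of the 3 splits of the 4 arrays into pairs, 1, the real split, gave 823 such probe sets, and the highest other gave 696. With 3 splits the share cannot fall under 0.05.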
